A study of Caenorhabditis elegans with 2 samples.

How the data were processed

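Chromatin immunoprecipitation followed by sequencing was carried out on whole Caenorhabditis elegans at the fourth larval stage, aged 66 hours and synchronised by starving hatchlings obtained by bleaching. The animals carried a transgene in which the product of tag-97 was fused to enhanced green fluorescent protein, and the fusion was precipitated with an antibody against that protein. The labels name svh-5 as the gene at which the tagged insertion is aimed and list an unc-119 rescue marker on the same transgene. The gene models used here hold no gene called tag-97, so tag-97 and svh-5 were assumed to be the same gene. Chromatin was sonicated to 200 to 800 bp. There were 2 biological replicates of 1 group, so no contrast between conditions was possible, and a control immunoprecipitation was not analysed here.

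The starting material was 8 deposited region lists on the ce11 build. Of these, 4 were ranked lists and 4 were thresholded lists, each for replicate 1, for replicate 2, for the 2 replicates against each other and for a joint ranking. The ranking used the irreproducible discovery rate (IDR), which scores how well regions hold their rank between 2 inputs. Peak caller, aligner and their versions are not given in the sources used here. The score column deposited by the authors is a whole number that rises with reproducibility, and a score of 830 stands for a global IDR of 0.01. The signal column deposited by the authors is the region's own value from peak calling, on an unstated scale, and was used only to describe or order regions within a list. The ranked lists deposited by the authors also hold the −log10 of the global IDR, which was turned back into an IDR here. In the list that ranked the replicates against each other, the deposited signal of the matched region in each replicate was read as well, with no scaling between replicates. Read counts were not analysed here, so depth per replicate is unknown and no interval that needs it is given. The checksums of all 8 lists matched those in the deposited file listing.

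Where each list came from was tested on the lists themselves. In the ranking of replicates, 80659 and 61427 of the 114284 regions had member regions that recurred in the lists of replicates 1 and 2. In the joint ranking of 118176 regions, 0 and 0 did, so its inputs were other than the replicates' own regions. The 321 regions of the joint thresholded list all had an IDR at or below 0.01, whereas a threshold of 0.05 had been assumed in the plan. The planned stricter threshold of 0.01 therefore left every value as it was. A further 75 regions met the 0.01 threshold in the joint ranking and were missing from the thresholded list, which points to an additional region filter that the sources used here do not describe. The joint thresholded list was used for every main result. The list from ranking the replicates against each other, with 182 regions, is called the conservative list.

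Regions were placed on the reference genome of the same assembly, with Ensembl release 115 gene models. A summit counted as lying at a promoter when it fell between 1000 bp upstream and 200 bp downstream of the annotated 5′ end of any gene. The share at promoters was tested against 1000 random placements within the same chromosome (one-sided) and, with Fisher's exact test (two-sided), against ranked regions that did not pass. Gene lists were tested with Fisher's exact test (two-sided) against other protein-coding genes, or against all other genes of any kind for the lists of RNA genes and pseudogenes, with Benjamini-Hochberg adjustment over the 31 lists that had at least 5 members. Intervals on shares of genes are exact binomial ones at 95% and cover counting error only. Overlap of the replicates' lists, at 1 bp or more, was tested by 1000 random placements (one-sided). Median signals were compared by permutation with 100000 resamples (two-sided), over regions, which are not biological replicates. Words of 6 bases, with both strands as 1, were counted in 101 bp around summits and compared by a one-sided Fisher's exact test with up to 10 ranked regions per listed region, matched on GC content in bins of 5 percentage points and on promoter state. The number of places in the genome to which each region's sequence aligned was found with blastn 2.17.0, counting alignments of at least 100 bp at 80% identity or more, so that shorter regions count as 1. Other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Coordinates are 1-based. A segment of raised signal was sought, after the lists had been examined, from ranked regions that did not pass. Their median signal was taken in bins of 100 kb with at least 20 regions. Bins more than 3 scaled median absolute deviations above the median of all 1004 bins were joined where at most 1 bin lay between them, and the longest run was used.

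Groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. Genes were named if they belonged to the 25 regions of highest signal, if they were among the 4 members with the highest signal of any gene list, if they were svh-5 or unc-119, or if they belonged to the 10 strongest regions found in both replicates' own lists. Outside promoter windows the gene with the nearest 5′ end was named, with its distance. Genes or regions named outside that rule are said to have been chosen after their values were seen. Alternatives covered the conservative list, each replicate alone, an IDR of 0.01 or 0.05 without the region filter, an IDR of 0.001 within the list, narrower and wider promoter windows, whole-region overlap, protein-coding genes alone, regions near structural RNA genes left out, 1 region per group of similar sequences, the segment of X left out, other word windows and other backgrounds.

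The planned tests were tried on simulated data of the same size, the promoter share by Fisher's exact test alone. Its random placement, the location categories and the comparison of regions on X were not simulated. Simulated regions were drawn or placed independently. Of the 321 listed regions, 91 lay in 1 segment of X and 71 fell into groups of similar or overlapping regions. The rates below may therefore not hold for lists clustered in that way. With nothing planted, 6 of 100 draws passed for the promoter share, 2 of 100 for genes on X, 8 of 100 for the promoter signal and 1 of 20 for replicate overlap. At least 1 gene list was called enriched in 7 of 100 such draws, and no word passed in any of 10. The test called 21U piRNA genes depleted in 60 of 100 draws with nothing planted, so that call carries no weight. Planted effects were recovered in 100 of 100 draws for a promoter share of 57%, in 100 of 100 for 10 regions at ribosomal protein genes, in 97 of 100 for a 41% share of regions on X, in 90 of 100 for a signal factor of 1.3 and in 20 of 20 for 30 shared regions. A word planted in 10% of regions was found in 10 of 10 draws and one planted in 5% in 5 of 10.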

Results

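The series mapped where a tagged tag-97 fusion protein was found on chromatin in whole L4 animals. The 2 biological replicates gave 70 and 71 regions in their own thresholded lists, 182 in the conservative list and 321 in the joint list. The joint regions had a median width of 296 bp and merged into 304 where they overlapped. Their median signal was 72.6, with a range of 2.92 to 264. Overlapping regions were counted separately in the tests over regions. A second group of animals was not analysed here, so each comparison below sets regions against other regions, genes or random positions.

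The first comparison asked how far the replicates found the same regions. Of the 70 regions of replicate 1, 30 overlapped a region of replicate 2, against a mean of 0.036 and a maximum of 2 when regions were placed at random (permutation p = 0.000999, the smallest that 1000 placements can give). These shared regions included the promoters of the HSP70 family pair F44E5.4 and F44E5.5, the RNA helicase gene mog-4, the ribosomal protein gene rpl-3 and the replication protein A gene rpa-2. Of the 30 joint regions present in both replicates' lists, 18 lay at promoters and 3 on chromosome X, and their median signal was 141. The other joint regions were less evenly supported. In all, 62 were in the list of replicate 1, 68 in that of replicate 2, and 221 in neither, while 159 were in the conservative list. Across regions, which are not independent replicates, signals in the replicates had a Spearman correlation of 0.203 over the 320 joint regions that recurred in the ranking of the replicates against each other, 0.330 over the conservative list and 0.162 over all 114284 ranked regions.

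**Figure D1:**
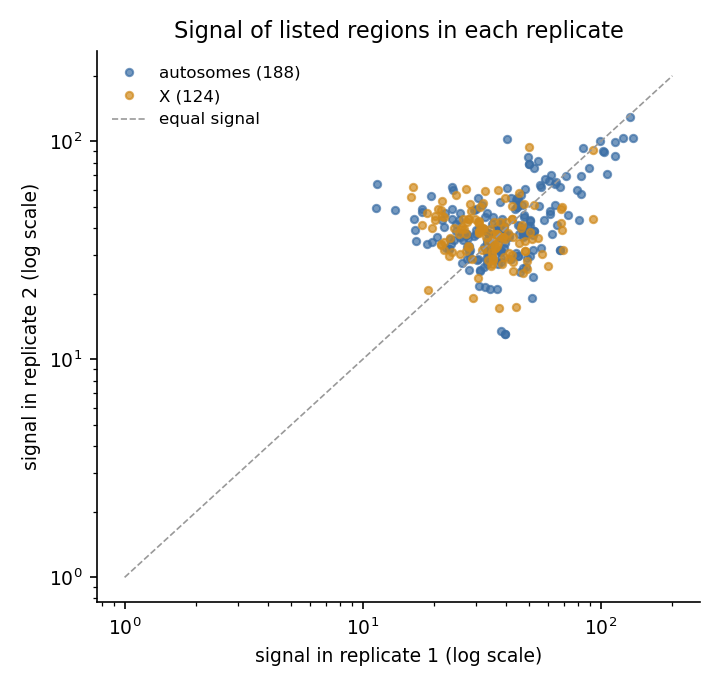
Signal of joint-list regions in replicate 1 (x axis) and replicate 2 (y axis), both in the authors' signal units on log axes, with 1 point per region for the 312 regions plotted (124 on X, 188 on autosomes), 9 regions on X being left out for want of an overlapping region in a replicate's own ranked list. Above a signal of 90 in both replicates lay 7 regions, and the highest values were autosomal (137 in replicate 1 and 130 in replicate 2, against 93.2 and 94.5 on X).

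The strongest region lay between F44E5.4 and F44E5.5, divergent heat-inducible HSP70 genes (II:11759282-11759577). Its signal was 264 in the joint list, 133 in replicate 1 and 130 in replicate 2, and its summit was 232 bp upstream of the 5′ end of F44E5.5. Next came the promoter of mog-4, which encodes a DEAH-box helicase of the sperm-to-oocyte switch (II:14561795-14561941, signal 245, replicates 137 and 103.8, 271 bp upstream). A region at the noncoding RNA gene WBGene00195021 had a signal of 226 (IV:4725542-4725671). The promoter of rpl-3 had 216 (III:3867497-3867616, replicates 115.1 and 99.7). The region 647 bp upstream of rpa-2 and 582 bp upstream of the long noncoding RNA gene M04F3.7 had 204 (I:4769497-4769792). A region of signal 197 was shared by cux-7, the DNA ligase IV gene lig-4 and C07H6.2 (III:7520712-7521007), one of 196 by wbp-4 and F56G4.6 (I:11374405-11374500), and one of 186 lay upstream of cnk-1, a scaffold of Ras signalling (III:10270814-10271109).

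Further promoters among the 25 strongest regions belonged to the pseudogene WBGene00023323 (185), tasp-1 with K01G5.10 (156), C47E8.4 (146), the ubiquitin ligase gene eel-1 (136) and sco-1, a copper chaperone gene of cytochrome oxidase assembly (135). They also included mtcu-2 (135), rpl-20 with Y17G9B.5 (135), W04C9.4 (134), dnj-28 with supr-1 (133) and rpl-35 (130). The 7 regions outside promoter windows lay nearest to the following 5′ ends. Upstream were those at F07H5.7 (185, 2436 bp), the transfer RNA gene WBGene00014538 on X (181, 1480 bp) and K02D3.5 on X (136, 3033 bp). Downstream were those at the pseudogenes WBGene00023318 (170, 1052 bp), WBGene00014975 (156, 1886 bp) and WBGene00013722 (134, 4917 bp) and at 21ur-1671 (134, 1313 bp). All 25 were in the conservative list and 21 were in the lists of both replicates. Repeated sequence underlay some of them: the regions at mog-4, WBGene00195021 and rpa-2 aligned to 9, 8 and 8 places in the genome, those at mtcu-2, eel-1 and dnj-28 to 22, 62 and 79, and those at F44E5.4 and rpl-3 to 1.

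The next comparison asked whether regions favoured the 5′ ends of genes. Summits of 182 of the 321 regions (56.7%) lay in promoter windows, against a mean of 33.5% (95% of draws between 28.7% and 38.6%) for random placement (p = 0.000999, the smallest possible) and 32.8% of ranked regions that did not pass (odds ratio 2.68, Fisher's exact p = 1.99e-18). Coding exons held 39 regions, 12.1% against 23.02% of ranked ones (odds ratio 0.463, Fisher's exact adjusted p = 1.73e-06), and introns 42, 13.1% against 24.6% (odds ratio 0.461, adjusted p = 1.18e-06). The 49 intergenic regions made up 15.3%, against 15.7% of ranked regions, and 9 lay in other exons. Promoter windows held 122 of 188 autosomal regions (64.9%) and 60 of 133 on X (45.1%), a lower share on X (odds ratio 0.445, Fisher's exact p = 0.000581). Most X regions lay in 1 segment, described with the chromosomes, where the share was 46.2%; on the rest of X it was 18 of 42 (42.9%, odds ratio against autosomes 0.406, Fisher's exact p = 0.0136). Of the 39 regions in coding exons, 31 were in that segment, 1 on the rest of X and 7 on autosomes. With protein-coding 5′ ends alone, 38.3% of summits were at promoters, a share that cannot be set against those above, whose windows cover genes of every kind. It was above the matching share of ranked regions, with a Fisher's exact p under 0.05.

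Promoter windows with a region belonged to 302 genes, of which 151 were protein-coding, and the gene lists asked which functions these genes serve. Cytosolic ribosomal protein genes were the most enriched group: 10 of 82 had a region (12.2%, exact 95% interval 6.01% to 21.3%), against 0.709% of other protein-coding genes (odds ratio 19.5, exact test with adjusted p = 4.7e-09). The 10 were rpl-3 (signal 216), rpl-20 (135), rpl-35 (130), rpl-15 (111.9), rps-24 (111.8), rps-23 (99.2), rps-26 (86.5), rpl-43 (77.9), rla-1 (76.7) and rpl-7A (65.3). Those after rpl-15 fall outside the naming rule and were chosen after their values were seen. The region at rps-24 aligned to 47 places in the genome. Heat shock protein and chaperone genes held 4 regions among 66 members (6.06%, odds ratio 8.67, exact test with adjusted p = 0.00813). These were at the DnaJ genes dnj-28 (133) and dnj-13 (105), the HSP70 cochaperone gene bag-1 (103) and the mitochondrial chaperonin gene hsp-60 (85.99). F44E5.4 and F44E5.5 were outside that list, whose members were taken by gene name. Among 56 genes of mitochondrial oxidative phosphorylation, 3 had a region (5.36%, odds ratio 7.56, exact test with adjusted p = 0.0388): the cytochrome oxidase subunit genes cox-5B (91.2) and cox-5A (75.8) and the ATP synthase subunit gene atp-5 (64.4). Replicate 2 alone kept the ribosomal protein and chaperone calls. Replicate 1 alone kept the former, but gave an exact-test adjusted p = 0.0571 for chaperones, and the oxidative phosphorylation call was lost in either replicate alone (adjusted p of 0.497 and 1) and in the conservative list (0.122).

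Short structural RNA genes formed the other enriched groups. Small nucleolar RNA genes, whose products guide modification of ribosomal RNA, held regions at 22 of 346 members (6.36%, odds ratio 11.2, exact test with adjusted p = 2.26e-14). The highest signals were at C51F7.3 and C51F7.4 (127, 1 region) and at K11H12.12 and K11H12.13 (111.9, 1 region). Transfer RNA genes held regions at 26 of 612 (4.25%, odds ratio 7.40, exact test with adjusted p = 5.39e-13), led by WBGene00023221 (106), the neighbours WBGene00014333 and WBGene00014334 (97.3) and WBGene00023050 (95.1). Of these, 17 were among 276 transfer RNA genes on X (odds ratio 5.10), 8 of them in the segment described with the chromosomes, and 9 among 336 on autosomes (odds ratio 5.47). The transfer RNA call was lost in replicate 1 alone (odds ratio 1.304, exact test with adjusted p = 1) and at an IDR of 0.001 (4.14, adjusted p = 0.249). Of the 10 regions at ribosomal protein genes, 4 were also at small nucleolar RNA genes; the one at rpl-15, for example, was that of K11H12.12 and K11H12.13. Small nuclear RNA and spliced leader genes, including R07E5.16 (98.2), sls-2.4 (77.5) and M163.13 (71.8), had 3 of 129 (exact test, adjusted p = 0.198).

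Pseudogenes had fewer regions than other genes, 3 of 2128 (odds ratio 0.210, exact test with adjusted p = 0.00721), namely WBGene00023323 (185), WBGene00020295 (111.8) and WBGene00164983 (81.1). Against ranked regions in place of genes, the pseudogene odds ratio was 0.401 (exact test, adjusted p = 0.370), and the call was lost in 8 of 15 other settings, among them the conservative list (adjusted p = 0.246), either replicate alone (adjusted p = 1) and regions near structural RNA genes left out (adjusted p = 0.237). For 21U piRNA genes, which lie in dense clusters, 17 of 15363 had a region (odds ratio 0.121), led by 21ur-11151 (109), 21ur-12493 (77.4), 21ur-15354 (76.4) and 21ur-13751 (72.3). The matching odds ratio over regions was 0.813 (exact p = 0.646), and simulated lists with nothing planted often gave the gene-level call.

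Several lists had 1 to 3 members with a region and did not pass. The translation factor gene iff-2 (89.8) was 1 of 40, and prp-19 (99.98) was 1 of 70 splicing genes. The calponin gene cpn-3 (79.6) was 1 of 47 muscle genes and the Runx factor gene rnt-1 (67.4) 1 of 32 hypodermis and seam genes. The transporter gene pgp-5 (73.5) was 1 of 268 stress and detoxification genes, and cel-mir-52 (80.3) was 1 of 261 microRNA genes. Of 274 nuclear hormone receptor genes, 3 had a region: the dauer regulator daf-12 (69.8), also 1 of 26 molting and heterochronic genes, nhr-141 (68.2) and the sex determination gene sex-1 (48.6). No member had a region among 27 genes of svh, JNK and p38 signalling, 81 histone, 177 cuticle collagen, 98 homeobox, 33 intestine, 53 neuron, 23 pharynx, 133 germline and sperm or 411 innate immunity genes. The same held for 61 insulin and longevity, 21 vacuolar ATPase, 33 proteasome, 28 Wnt, 33 vulval signalling and 20 ribosomal RNA genes. None of these 15 lists was depleted by its test, innate immunity having the smallest p (exact 0.0797, adjusted 0.275). Each already had the lowest count possible, so lists of these sizes could not have been called depleted, and the tests do not speak on depletion.

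**Figure D2:**
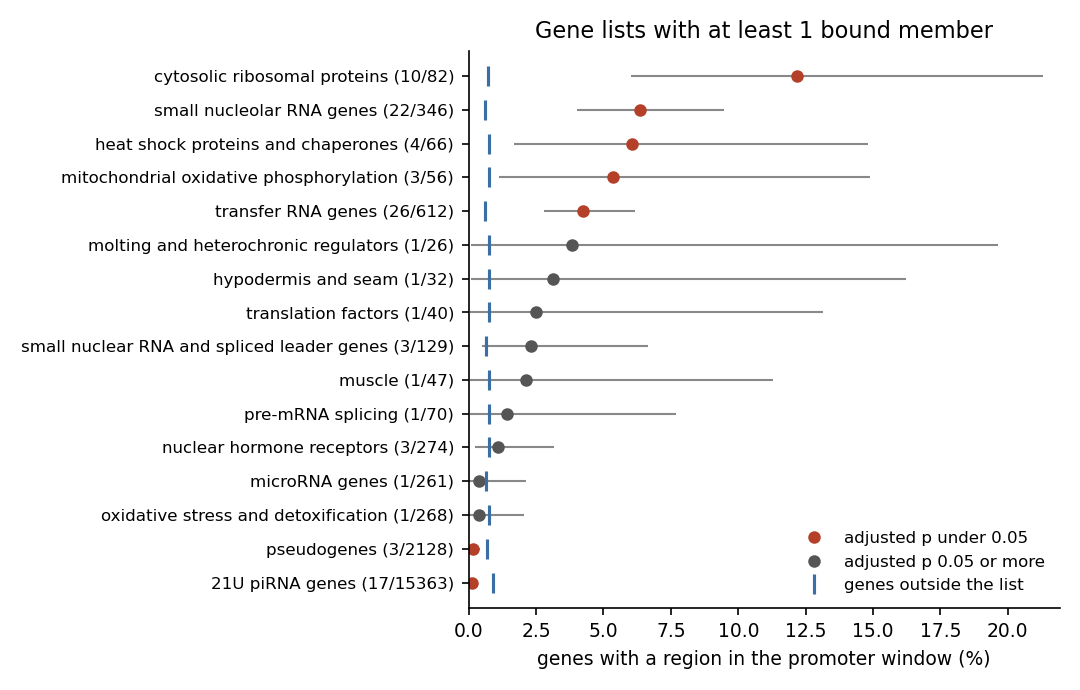
Percent of each list's genes with a region in the promoter window (points), with exact 95% binomial intervals (grey lines) and the percent among genes outside the list (blue ticks), for lists with at least 1 such gene. Red points passed at an adjusted p under 0.05: ribosomal protein genes stood highest at 12.2% and 21U piRNA genes lowest at 0.111%.

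Chromosome X carried more regions than its length would give, and the excess lay in 1 segment. X held 133 regions, 7.51 per Mb, against 2.28 per Mb on the autosomes, where chromosomes ranged from 1.67 (V) to 2.97 (III). X regions made up 41.4% of the joint list and 17.6% of ranked regions that did not pass (odds ratio 3.31, Fisher's exact p = 2.43e-23). Of the 133, 91 lay between 9.1 and 11.6 Mb (36.4 per Mb), and the other 42 made 2.76 per Mb, inside the autosomal range. With the segment left out, the odds ratio of X was 1.20 (Fisher's exact p = 0.276). Signal was raised along the whole segment: ranked regions there that did not pass had a median signal of 25.3, against 18.5 on the rest of X, and the ratio of medians was 1.42 in replicate 1 and 1.302 in replicate 2. Of 1004 bins of the genome, 24 had a raised median, all of them among the 25 bins of this segment, which was set from those medians and not from listed regions. Ranked regions were no denser there, at 1089.6 per Mb against 1184.8 on the rest of X.

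The excess over all of X was present in the conservative list (odds ratio 3.08), in replicate 1 (2.47) and in replicate 2 (1.89, Fisher's exact p = 0.0197). In these lists 44 of 72, 11 of 24 and 15 of 21 X regions lay in the segment. The replicates mostly differed in their X regions, as only 3 of the 30 joint regions in both replicates' lists were on X. The excess was absent from the top of the joint list: X had 7 of the 50 strongest regions (14%), 22 of the next 50 (44%) and 51 of the next 100 (51%). Among the 52 regions with an IDR of at most 0.001, 8 were on X (odds ratio 0.850, Fisher's exact p = 0.855). The comparisons of regions and of the segment were added after the data were examined. In the planned comparison of protein-coding genes, 30 of 2731 on X (1.10%) and 121 of 17242 on autosomes (0.702%) had a region (odds ratio 1.57, Fisher's exact p = 0.0318). With the segment left out, genes on X had fewer regions, 6 of 2339 (0.257%, odds ratio 0.364, Fisher's exact p = 0.00858), so the planned result rested on the segment. The direction turned in 5 further settings, and in 2 of them genes on X again had fewer regions by the test: with replicate 2 alone (odds ratio 0, Fisher's exact p = 0.0119) and at an IDR of 0.001 (0, p = 0.00712). It also turned with replicate 1 alone (0.526), in the conservative list (0.769) and in a window of 500 bp upstream to 100 bp downstream (0.922).

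**Figure D3:**
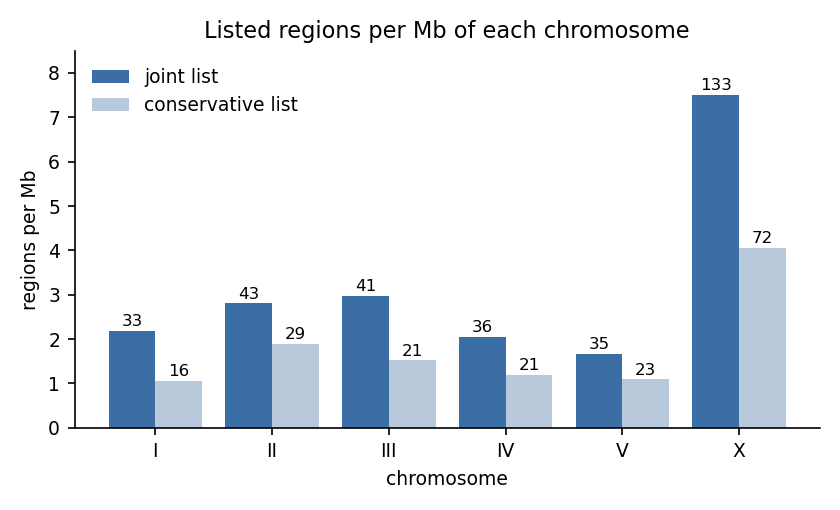
Listed regions per Mb of each chromosome (y axis) in the joint list (dark bars) and the conservative list (light bars), with the number of regions above each bar. X stood at 7.51 per Mb in the joint list with 133 regions, and no autosome exceeded 2.97 per Mb.

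**Figure D4:**
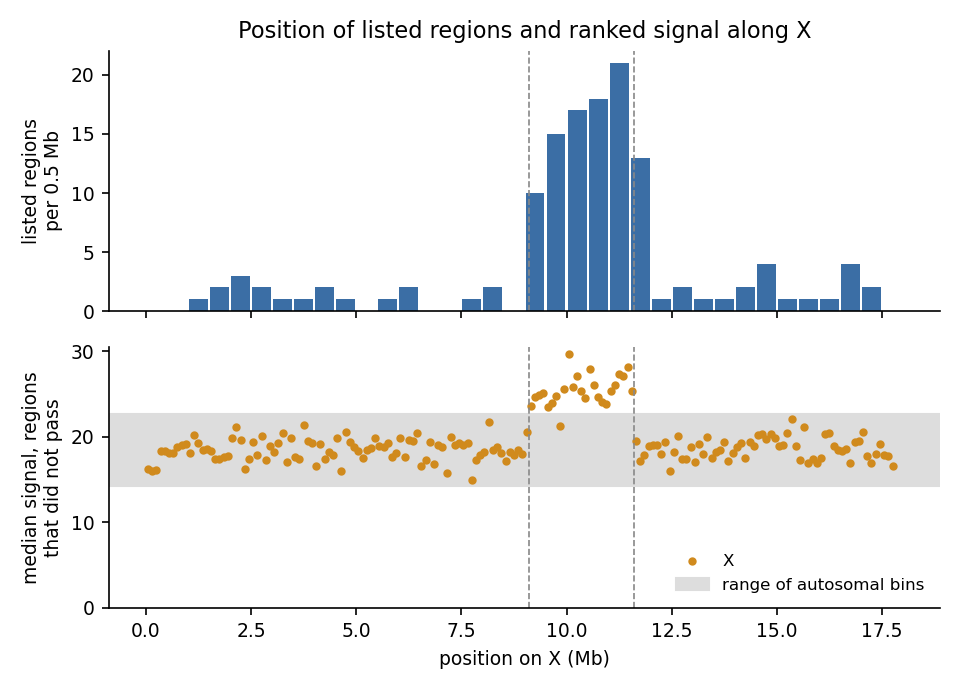
Number of joint-list regions per 0.5 Mb along X (upper panel, bars) and median signal of ranked regions that did not pass, in the authors' signal units, per bin of 100 kb (lower panel, points), with the range of autosomal bins in grey and the segment from 9.1 to 11.6 Mb between dashed lines. Bins in the segment had medians of 21.2 to 29.7, and no bin elsewhere in the genome exceeded 22.7.

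Regions at promoters had a median signal of 73.7 (n = 182) against 70.9 elsewhere (n = 139), a difference of 2.83 that did not pass (permutation p = 0.0913). In the narrower window of 500 bp upstream to 100 bp downstream the difference was 4.13 and passed (permutation p = 0.0127). On autosomes the medians were 77.9 and 69.3, a difference of 8.63 (permutation p = 0.0159), whereas on X they were 71.6 and 71.7 (difference -0.175, permutation p = 0.875). Whether these differences themselves differ between X and autosomes was not tested. X and autosomal regions had median signals of 71.7 and 74.7 (permutation p = 0.0777).

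Short sequence words around summits were compared with matched ranked regions. Of 2078 words, 43 passed, and not all are separate findings. GGCCTA, read on the other strand, and CTAGGC both lie within CTAGGCCA, which was in 16 of 188 autosomal regions against 19 of 1880 matched ones. GGCCTA was in 33 of 321 regions (10.3% against 3.05%, odds ratio 3.64, exact test with adjusted p = 5.17e-05), CTAGGC in 28 (odds ratio 3.94, adjusted p = 6.84e-05), GTACAC in 27 (3.01, adjusted p = 0.00521), GGCCAC in 31 (2.62, adjusted p = 0.00978) and CTGCGC in 23 (3.06, adjusted p = 0.0109). Autosomal regions alone gave 65 passing words and X regions alone 0, as did the 91 regions of the X segment and the 42 on the rest of X taken apart. These sets on X are smaller, and the power of the test at their sizes was not simulated. The lack of a passing word therefore does not show that X regions share none. With the segment left out, 62 words passed. GGCCTA had an odds ratio of 4.82 on autosomes and 0.731 on X and CTAGGC 4.54 and 2.30. CTGCGC passed on neither, with 1.54 on autosomes (exact test, adjusted p = 0.878) and 3.38 on X (adjusted p = 0.384), and the difference between them was not tested. The count also moved to 8 in the conservative list, to 3 with replicate 2 alone and to 12 with replicate 1 alone. The windows searched for words had a median GC content of 47.5%, against 38.6% in ranked regions.

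The genes carried on the transgene were examined in any case. At svh-5 (X:15369974-15377824, minus strand), taken to be the gene fused under the name tag-97, the joint list had 0 regions. The conservative list had 2 overlapping ones, X:15373917-15374212 (signal 58.0) and X:15374146-15374441 (3.78). The summit of the first lay 3759 bp inside the gene from its 5′ end and outside any exon. That region had an IDR of 0.00799 when the replicates were ranked against each other (signals 38.8 and 32.8) and 0.0187 in the joint ranking. The nearest joint region (signal 79.1, F47C8.5) was 14881 bp away. Within 20 kb of svh-5, 6 ranked regions had an IDR of at most 0.05, against a mean of 1.11 at random places on X, of which 4.82% had as many. Those places took in the segment of raised signal, which can raise both values. Ranked regions within 20 kb of svh-5 had a median signal of 27.7, above that of 96.2% of random places, whose typical median was 18.9. Near unc-119 the medians were 19.5 and 18.6. The source of the raised signal near svh-5 was not tested. At the marker gene unc-119 (III:10902641-10908935) the joint, conservative and single-replicate lists had 0 regions, the strongest ranked region had a signal of 32.3 and an IDR of 0.224, and the nearest joint region, at oxi-1, was 45456 bp away.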

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

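The tests in this part were chosen only after the result was seen. The joint ranking held 75 regions that met the IDR threshold of 0.01 but were absent from the thresholded list, which drew attention because signal in them enters no main comparison above. Their median signal was 111, against 72.6 in the list (permutation p = 1e-05, the smallest possible), 14 of them (18.7%) lay in promoter windows and 16 were on X. The strongest, X:15810938-15811174, had a signal of 2069, the highest of the whole ranking, with 994 in replicate 1 and 1200 in replicate 2, and its summit lay 859 bp upstream of the pseudogene WBGene00044155. The next were X:293353-293481 (561) nearest to R57.2 and X:15808131-15808268 (407).

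Signal seen in 1 replicate only is argued against as the source of most of them, since 56 of the 75 had an IDR at or below 0.01 when the replicates were ranked against each other, as did 156 of the 321 listed regions and 29 of 117780 that did not pass. The bound of 50% used for that test was set when the count was known, in place of a looser overlap test. Sequence present in several copies of the genome may account for most of them: 89.3% aligned elsewhere in the genome, with a median of 12 copies, against 25.5% of listed regions (odds ratio 24.4, Fisher's exact p = 4.65e-25). This does not say which rule removed them, since 82 listed regions also aligned elsewhere. The 75 absent regions formed 45 clusters of neighbouring regions, so those counted in both tests were not independent of each other. With 1 group of animals and no control analysed here, no biological explanation was tested.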

How the results depend on the processing

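Chosen only after the result was seen were the settings without the region filter, with an IDR of 0.05 or 0.001, with 1 region per group of similar sequences, on X or autosomes alone, with the segment of X left out and against ranked regions, all settings for regions on X and svh-5, and the conservative list for the number of regions. The promoter share kept its direction and side of the threshold under all 15 settings (38.3% to 72.3%), replicate overlap under all 6, and ribosomal protein genes under all 15. Transfer RNA and small nucleolar RNA genes have no value with regions near structural RNA genes left out, by construction. The planned IDR of 0.01 changed nothing, as the list already met it.

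The number of regions was 182 in the conservative list, 70 to 71 in 1 replicate alone, 1231 at an IDR of 0.05 without the region filter and 52 at 0.001, where fewer or more regions enter by construction. Enriched gene lists numbered 2 to 4 in 1 replicate alone, 3 at 0.001 and 3 without structural RNA regions. Oxidative phosphorylation genes had an odds ratio of 0 to 10.3 in 1 replicate alone and of 0 at 0.001. For genes on X the odds ratio was 0.769 in the conservative list, 0 to 0.526 in 1 replicate alone, 0 at 0.001, 0.922 in the narrow window and 0.364 with the segment of X left out. For regions on X it was 0.850 at 0.001, 1.20 with the segment left out (Fisher's exact p = 0.276), and stayed above 1 under the other 11 settings. The promoter signal difference was -2.65 at 0.01 and 1.52 at 0.05, both without the region filter, and 4.13 in the narrow window, of which 1.52 and 4.13 passed (permutation p of 0.0188 and 0.0127), -0.175 on X and 8.63 on autosomes.

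Passing words numbered 8 in the conservative list, 3 to 12 in 1 replicate alone, 27 at 0.01 and 2 at 0.05 without the filter, 18 at 0.001, 6 in 51 bp, 169 against flanks, 0 on X and 65 on autosomes. On X, GGCCTA, GTACAC and GGCCAC had odds ratios of 0.731, 0.231 and 0.921, CTAGGC 2.30 and CTGCGC 3.38, and on autosomes CTGCGC fell to 1.54. Regions in svh-5 numbered 2 in the conservative list and 1 at 0.05 without the filter. Beyond changes in how many regions were tested, the cause was not tested. Depth is unknown, so regions missed for lack of reads cannot be counted.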

Other observations

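Apart from the test of a uniformly higher background on X and the count of the motif outside the list, the tests in this part were chosen only after the result was seen. Similar sequences recurred among the listed regions. When regions that overlapped or aligned to each other were grouped, 71 of the 321 fell into groups, and the largest group held 8 regions, all at promoters and none on X. Its regions aligned to a median of 68.5 places in the genome and lay in promoter windows of genes that included eel-1, dnj-28, supr-1 and rps-24. The genes also included nrde-2, npp-6, mzt-1, atad-3 and Y62F5A.12, chosen here after their values were seen. Among words of 8 bases on autosomes, AGTCAGCC was in 11 of 188 regions and 1 of 1880 matched ones (exact test, adjusted p = 3.19e-07). Words of 8 bases were not recounted with 1 region per group of similar sequences. Copies of the same sequence may therefore have been counted as separate regions in that test. On X, where no word of 8 bases passed, the top ones overlapped each other, among them CGCAGGGA in 6 of 133 regions against 3 of 1320 (exact test, adjusted p = 0.105).

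The excess of regions on X was set against technical explanations, since it came with a signal raised along the segment from 9.1 to 11.6 Mb. Extra copies of the tagged locus are argued against, provided that svh-5 is that locus, since it lies outside the segment. With 1 Mb on each side of svh-5 left out the odds ratio was 3.53. That value adds no further support, because the cut spares the segment. A uniformly higher background on X is argued against too: after X signals were divided by the ratio of medians (1.04), X kept 37.1% of the strongest regions, above 22.4%, the upper bound of the 95% binomial interval of the ranked share. Signal raised along the segment as a whole was large enough to give most of the excess: with segment signals divided by their own ratio (1.37), the X share fell from 41.4% to 21.5%, within that bound, though the segment kept 17 of the strongest regions (5.30%, upper bound 4.44%). The division lowers every region of the segment alike, so it cannot tell a raised background from binding. Whether the segment was present in extra copies in these animals, was low in a control or was bound broadly was not tested, as neither reads nor a control were analysed here.

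CGCAGGGA lies within TCGCGCAGGGAG, the 12-base motif known from sites on X that recruit the dosage compensation complex, which lowers expression from X in hermaphrodites. At least 11 of the 12 bases were found within 150 bp of the summit in 8 of 133 listed X regions and 0 of 188 listed autosomal ones, but the motif had been noticed in those same regions. It was therefore counted in X regions outside the list: 3 of 279 with an IDR between 0.01 and 0.05 held it, against 7 of 20476 of higher IDR (odds ratio 31.8, Fisher's exact p = 0.000269). Regions that overlapped listed ones were not left out, and GC content was not matched, so this count is not an independent check. Recruitment sites are no more than a candidate source of the regions that carry the motif. The 8 listed regions that carry it were too few to make up the X excess: the odds ratio without them was 3.11, and 7 of the 8 lay outside the segment. Recruitment sites with weaker matches to the motif were not tested as its source.

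The 8 regions, picked here after their values were seen, included both exact matches, X:11094045-11094340 (signal 181), the strongest listed region on X and the only one of them in the segment, and X:2996955-2997250 (116.4). All 8 aligned to 1 place in the genome, 7 were in the conservative list and 3 lay in promoter windows. With 1 group of animals, no biological explanation of the X excess can be tested against another condition, and the hypothesis rests on the same lists that raised it.

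For ribosomal protein, small nucleolar RNA and chaperone genes no biological explanation was tested, as the design has 1 group. Sharing of regions with neighbouring small nucleolar RNA genes is argued against as the whole cause for ribosomal protein genes: with 48 regions near structural RNA genes left out, 5 ribosomal protein genes remained, with an odds ratio of 10.3 (exact test, adjusted p = 0.00306). An equal effect of open promoters across widely expressed genes is argued against as the whole cause for ribosomal protein genes. Translation factor, proteasome, vacuolar ATPase, splicing and oxidative phosphorylation genes held a region at 5 of 220 members, less often than ribosomal protein genes (odds ratio 5.97, Fisher's exact p = 0.00121). Their share was still above that of other protein-coding genes (odds ratio 3.43, Fisher's exact p = 0.0185). Without oxidative phosphorylation it was 2 of 164 (Fisher's exact p = 0.314). Neither openness nor expression was measured, so an effect graded by either was not tested. An effect of open promoters stays open for ribosomal protein genes and, against the share of 2.27%, for chaperone genes (odds ratio 2.77, Fisher's exact p = 0.219), which are too few. It was not tested for small nucleolar RNA genes. A higher yield of particular heavily transcribed loci in any immunoprecipitation stays open for all of them, because a control was not analysed here.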
